A study of Mus musculus with 167 samples.

How the data were processed

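Liver RNA of male C57BL/6 mice was measured on Affymetrix GeneChip mouse expression arrays, with 1 biotin-labelled array per animal, in 3 genotypes, 2 arms and 6 days. Genotype, treatment, day and animal number were taken from the labels, per which animals were assigned at random and phenobarbital was given in the drinking water. The treatment text also lists lower concentrations and another starting age, and no sample's own label gives a dose, so that 0.05% rests on that text. The animal number is printed where a single animal matters. Per the submitters' processing notes the values were made with RMA, which corrects the background, normalizes probe intensities across arrays by quantiles and summarises them per probe set. The version of RMA, and whether all arrays passed through it together, are not given in the sources used here. The deposited values are log2 expression, as their range shows: they lay between 2.11 and 15.07, and the 167 array medians between 5.146 and 5.231. All values and differences are on this log2 scale, which RMA compresses for weak and for near-saturated probe sets. Replicates are separate animals per the labels. No scan date or hybridisation batch was used here.

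The deposited array values covered 45101 probe sets, 64 of them the manufacturer's controls, with 0 sample columns left unused. Gene symbols came from the platform annotation, in which 34958 probe sets had 1 symbol, 932 several and 9211 none. Symbols were matched through Entrez numbers to a RefSeq gene table of assembly GRCm38.p6 for 34754 probe sets, which renamed 0 of them. The RefSeq genes served only for names and for which genes neighbour each other. Probe sets with several symbols or none were left out. Of several probe sets for a gene, the one with the highest mean log2 value over all arrays stood for it. A gene was tested where at least 3 arrays lay above their own array's median, which kept 12622 of 18193 genes and left out 5571 as dim.

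Before the fit, all 13861 pairs of arrays were compared over 2706 genes with a mean log2 level of at least 9. In 2 pairs no gene differed by over 2-fold, and the SD of the log2 difference was 0.0613 for animals 6026 and 6030 and 0.056 for animals 4019 and 4024, against at least 0.1221 in every other pair. The former pair carries 1 set of labels, treated humanized on day 119, and was averaged to 1 sample. The latter carries different days of the treated knockout, so that at least 1 label may be in doubt, and both arrays were kept as labelled. The fit therefore held 166 samples.

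Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided). The model had 36 group means, of genotype, treatment and day, with 130 residual degrees of freedom, a prior of 3.98 degrees of freedom and a prior SD of 0.119. From it came 28 contrasts. They are phenobarbital against control on each day, the mean effect over the 5 dosing days, the differences of that mean between genotypes, the day 91 minus day 1 differences in wild-type and humanized mice, and the controls of either altered genotype against wild-type controls over 6 days. P-values were adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. All groups entered 1 model because groups of 3 to 5 animals give a poor estimate of the spread on their own. The pooled spread assumes that groups vary alike, which the fit on only the compared groups tests.

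The 35 gene lists held 520 entries, of which 418 were tested. They covered drug metabolism and transport, the cell cycle, p53, Wnt signalling and zonation, the Dlk1-Dio3 domain, lipid, bile acid, glucose and haem metabolism, stress, inflammation, sex bias, the clock, hepatocytes and other cell types. Lists were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists within a contrast, which made 980 tests. Not every list call is printed. Camera sets a list against all other tested genes. Of 263 list calls, 102 also passed with an estimated correlation and 185 with fry, which tests whether a list's genes move one way on balance. Counts of list members are over all genes tested, and those adjusted over the list alone stand beside them where they differ. The animal score is the mean log2 level of a list's tested genes in 1 liver. Scores of the S phase and G2/M lists were compared by two-sided exact permutation tests, adjusted over a family of 36.

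Genes named in the text follow a rule. In any case 20 genes were to be named, of which 18 were tested, and Ccnb1 and Por were not analysed here. Of the genes called in a dosing-day mean with 1 sign on all 5 dosing days, the 8 largest rises and 6 largest falls were taken in wild-type and in humanized mice and the 4 largest each way in the knockout. For the other contrasts, except phenobarbital against control on single dosing days, the 5 largest each way were taken. For each list and contrast up to 4 called members were taken. Predicted genes without an official name were passed over. Tomm40l and Pcp4l1, neighbours of a targeted gene, were chosen after their values were seen.

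Groups, comparisons, tests, lists, the naming rule and the first set of alternatives were fixed before the data were examined. These alternatives were no filter on dim genes, all kept probe sets (25757), only the arrays of the compared groups, quantile normalization of the deposited values, eBayes with trend and robust, array weights, a 1.5-fold minimum, each animal left out in turn, and the probe set with the largest variance for named genes. Alternatives chosen after seeing the data were arrays 6026 and 6030 as 2 samples, the fit without arrays 4019 and 4024, the clock index or the mean of the pancreas acinar markers as a covariate, the list tests with each animal left out in turn, and splits with the day or genotype difference shared by both arms subtracted. For other splits of the samples, treatment was exchanged within days, genotype within treatment and day, or day within treatment, in up to 100 splits per comparison.

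The code was tested on simulated data with the group sizes and spread of the 12622 genes, with 50 changed genes per fold size. At 1.5-fold it recovered 92% of them in the wild-type day 1 comparison with 6 false calls over all fold sizes, 88% in that of the knockout on day 7 with 5, 100% in the wild-type dosing-day mean with 11 and 94% in the humanized minus wild-type difference with 12. In a simulated wild-type day 7 comparison, the 1 shifted list of 35 was called and 0 of the others. Other tools were the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.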

Results

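Transcript levels were measured in the livers of 167 male C57BL/6 mice with Affymetrix mouse GeneChip arrays, 1 array per animal. Mice were wild type, lacked the nuclear receptors CAR (gene Nr1i3) and PXR (gene Nr1i2), or carried the human receptors in place of the mouse ones. In each genotype, 1 arm drank water with 0.05% (wt/vol) phenobarbital, a barbiturate that activates CAR, and the other drank plain water. Livers were taken on days 1, 7, 14, 28 and 91 of dosing and on day 119, 4 weeks after dosing ended. The 36 groups held 3 to 5 animals on the array. The wild-type arms had 27 control and 29 treated animals, the knockout arms 27 and 28, and the humanized arms 29 and 27. Treated humanized animals 6026 and 6030 of day 119 differed by less than the noise between other pairs of arrays and were counted as 1 sample, which left 3 samples in that group. Knockout arrays 4019 (treated, day 28) and 4024 (treated, day 91) were also nearly identical although their labels differ, and both were kept as labelled. The series asks how liver transcripts, those of the cell cycle in particular, respond to phenobarbital when the human receptors replace the mouse ones. Differences are in log2 units of the fit, the value after ± is their standard error (SE) unless SD is written, and adjusted p-values of genes are limma's, two-sided.

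The targeted genes separated the genotypes in the direction of the labels. Nr1i3 averaged 8.34 ± 0.27 (SD, n = 56) in wild-type livers with a range of 7.74 to 8.91, against 4.95 ± 0.15 (SD, n = 55) in the knockout and 5.07 ± 0.15 (SD, n = 55) in humanized livers. Their highest values were 5.38 and 5.46. Nr1i2 averaged 7.55 ± 0.25 (SD, n = 56) in wild-type livers, 3.63 ± 0.14 (SD, n = 55) in the knockout and 3.72 ± 0.18 (SD, n = 55) in humanized livers. The lowest wild-type value of 6.91 lay above the highest of the others, 4.19. The human receptor transcripts were not analysed here. Phenobarbital lowered Nr1i3 in wild-type livers by a small amount over the dosing days (−0.20, adjusted p = 0.00136), while Nr1i2 did not pass the test there (0.05).

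In wild-type liver, phenobarbital raised genes of drug metabolism most, on average over the 5 dosing days (24 treated and 22 control animals). Cyp2b10, the cytochrome P450 used as the usual readout of CAR, rose by 6.50 ± 0.089, from 6.44 ± 0.37 (SD, n = 5) in controls to 12.94 ± 0.14 (SD, n = 5) on day 1. Cyp2c65 rose by 5.67 ± 0.075, Cyp2c55 by 4.39 ± 0.073 and Cyp2b9 by 3.07 ± 0.174. Outside the P450 family, the glutathione transferase Gstm3 rose by 3.01 ± 0.082, the sulfotransferase Sult3a1 by 2.94 ± 0.142 and Nebl, which encodes an actin-binding protein, by 2.28 ± 0.098. The pseudogene Serpina4-ps1 (−1.62 ± 0.338), the fatty acid hydroxylase Cyp4a14 (−1.47 ± 0.295), the lipoprotein lipase inhibitor Angptl4 (−1.29 ± 0.148) and the insulin-responsive Igfbp1 (−0.99 ± 0.246) fell most. Of 12622 genes tested, 3971 passed (1486 higher, 2485 lower), and 130 of these changed at least 1.5-fold (105 higher, 25 lower). Probe sets of near-identical family members such as Cyp2b9, Cyp2b10 and Cyp2b13 can share signal, so their separate values are uncertain.

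Among genes chosen beforehand, Gadd45b, a growth arrest and stress gene that CAR induces, rose by 1.21 ± 0.071 in wild-type liver. The imprinted non-coding RNAs Meg3 and Rian rose by 1.49 ± 0.073 and 1.14 ± 0.104. The replication helicase subunit Mcm5 rose by 0.67 ± 0.098, the proliferation marker Mki67 by 0.40 ± 0.095 (adjusted p = 0.000463), the topoisomerase Top2a by 0.35 and the mitotic kinase Cdk1 by 0.22. Cyp2c29 rose by 0.62 and Cyp3a11, a PXR target, by 0.12, while Glul, the glutamine synthetase of perivenous hepatocytes, fell by 0.19. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, passed at 0.48 ± 0.185 (adjusted p = 0.037), but not without animal 1017 (adjusted p = 0.0891). The Wnt target Axin2 (0.00) and the fetal marker Afp (0.12) did not pass. Albumin (Alb) was lower by a very small amount, −0.03, and did not pass with quantile normalization.

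The fixed gene lists describe the same response by function, with camera's p adjusted over the 35 lists. Where the count adjusted over the list alone differs from the count over all genes, it stands beside it. Of 22 phase I genes tested, 21 rose and none fell (adjusted p = 2.37e-71). Of 23 phase II conjugation genes 21 rose and 1 fell (adjusted p = 2.86e-51), among them Gstt3 (1.80). Of 12 hepatic transporters 6 rose and 2 fell (adjusted p = 0.000483), led by the efflux pump Abcc4 (1.81) and by Abcc3 (0.82). All 3 tested transcripts of the imprinted Dlk1-Dio3 domain rose (adjusted p = 2.09e-08). Of 9 female-biased liver genes 7 rose and 1 fell (adjusted p = 3.42e-13), with Cyp2b13 up by 1.93 ± 0.095. Of 10 NRF2 oxidative stress genes 5 rose (adjusted p = 0.000483). These calls also passed with an estimated correlation.

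The S phase replication list rose in wild-type liver as the mean of the dosing days, with 15 of 25 genes higher and 1 lower (16 and 1 adjusted over the list alone) and an adjusted p of 6.08e-06. Mcm6 (0.78), Mcm5 and the ribonucleotide reductase subunit Rrm2 (0.42) were higher, while the replication initiation factor Mcm10 fell (−0.49). That call was lost with an estimated correlation (adjusted p = 0.0922 with an estimated correlation). The G2/M mitosis list had 13 of 19 genes higher and none lower (adjusted p = 5.92e-07), among them the cytokinesis factor Ect2 (0.91), and was also lost (adjusted p = 0.0581 with an estimated correlation). Cholesterol synthesis genes rose in 18 of 20 cases and fell in 1 (adjusted p = 4.25e-10, and adjusted p = 0.199 with an estimated correlation), led by Sqle (1.22). Of 19 PPARα and fatty acid oxidation genes 14 fell and 2 rose (3 adjusted over the list alone), with Acot1 at −0.93 (adjusted p = 0.000661, and adjusted p = 0.305 with an estimated correlation). Of 11 periportal genes 7 fell (8 adjusted over the list alone; adjusted p = 0.00376, and adjusted p = 0.206 with an estimated correlation). Of 13 gluconeogenesis and glycogen genes 7 fell (adjusted p = 0.0305, and adjusted p = 0.305 with an estimated correlation), with Pck1 at −0.55. Of 8 interferon response genes 6 rose (adjusted p = 0.00368, and adjusted p = 0.265 with an estimated correlation). Of 8 hepatocyte markers 5 fell slightly (6 adjusted over the list alone; adjusted p = 0.00376, and adjusted p = 0.0578 with an estimated correlation).

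The other lists did not pass in the wild-type mean. The G1 and growth control list had 4 of 18 genes higher and 5 lower (5 and 5 adjusted over the list alone; adjusted p = 0.547), with Gadd45b and Myc (0.61) among those higher. The p53 target list had 2 of 15 higher and 5 lower (adjusted p = 0.747), the Wnt and perivenous list 4 of 16 higher and 4 lower (adjusted p = 0.28), and the bile acid list 2 of 14 higher and 4 lower (2 and 5 adjusted over the list alone; adjusted p = 0.595). Lipogenesis genes were higher in 3 and lower in 1 of 17 cases (adjusted p = 0.113), ER stress genes in 3 and 1 of 15 (adjusted p = 0.28), and haem synthesis genes in 2 and 0 of 7 (adjusted p = 0.257), with Alas1 up by 1.09. Acute phase genes were higher in 4 and lower in 5 of 19 cases (adjusted p = 0.916), with the acid glycoprotein gene Orm3 up by 1.26. Male-biased genes were higher in 2 and lower in 6 of 12 cases (adjusted p = 0.238), clock genes lower in 3 of 16 (adjusted p = 0.902), and none of the 8 oncofetal genes passed (adjusted p = 0.916). Among markers of other cells, stellate genes were lower in 3 of 10 cases (adjusted p = 0.412), cholangiocyte markers higher in 1 of 5 (adjusted p = 0.257) and Kupffer cell markers lower in 1 of 11 (none adjusted over the list alone; adjusted p = 0.833). No endothelial, T and NK cell, neutrophil, pancreas acinar, adipose or erythroid marker passed (adjusted p = 0.868 at least). Of 4 B and plasma cell markers Ighm alone rose, by 1.64 (adjusted p = 0.226 for the list).

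The cell cycle lists passed at early days of wild-type dosing. On day 1, 14 of 25 S phase genes rose in wild-type liver (15 adjusted over the list alone; adjusted p = 6.36e-13), with Mcm5 up by 1.38, and 6 of 19 G2/M genes rose (adjusted p = 0.000193, and adjusted p = 0.245 with an estimated correlation). The G2/M call was lost without treated animal 2004, where 1 gene was higher (adjusted p = 0.177), and 3 were higher without control 1003. The S phase list passed without animal 2004 with 7 genes higher (adjusted p = 9.67e-08). The calls for Mki67 (0.63), Ect2 (0.87), Top2a (0.78) and Rrm2 (1.09) were lost without it (adjusted p = 0.581, 0.116, 0.0628 and 0.101). The G2/M score of animal 2004 was 6.61, against 5.60 to 5.93 in the other treated animals. Its mean over the pancreas acinar markers was 9.11, against 4.85 to 6.75 in those animals and 5.22 to 10.14 in controls. On day 7, 10 G2/M genes rose (14 adjusted over the list alone; adjusted p = 4.8e-25), with Ccnb2 up by 1.86 (adjusted p = 1.39e-10), Ect2 by 1.79 and Birc5 by 1.42. The S phase list also rose on day 7, with 7 genes higher (15 higher and 1 lower adjusted over the list alone; adjusted p = 1.76e-10). That count was 4 without animal 1010 or 2007, 3 without 2008 and 11 without 2009. On day 14 the G2/M list passed (adjusted p = 0.0154) with 1 gene lower (none without 1012, 1013, 1014, 2011, 2012 or 2013), none higher (none adjusted over the list alone) and a median of 0.16. It was lost with an estimated correlation (adjusted p = 0.466 with an estimated correlation) and with quantile normalization (adjusted p = 0.0788). The S phase list did not pass on days 14, 28 and 91 (adjusted p = 0.202, 0.554 and 0.255), nor did the G2/M list on days 28 and 91 (adjusted p = 0.445 and 0.192). The animal scores, the mean log2 level of a list in each liver, were compared by two-sided exact permutation tests in a family of 36. The S phase score on day 1 was 7.08 ± 0.3 (SD, n = 5) with phenobarbital and 6.67 ± 0.06 (SD, n = 5) without, 4 treated animals above every control (exact p = 0.0159, adjusted 0.0716). The G2/M score on day 7 was 6.24 ± 0.24 (SD, n = 4) against 5.57 ± 0.13 (SD, n = 4), all 4 treated animals above every control (exact p = 0.0286, the smallest the design allows, adjusted 0.0858).

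**Figure D1:**
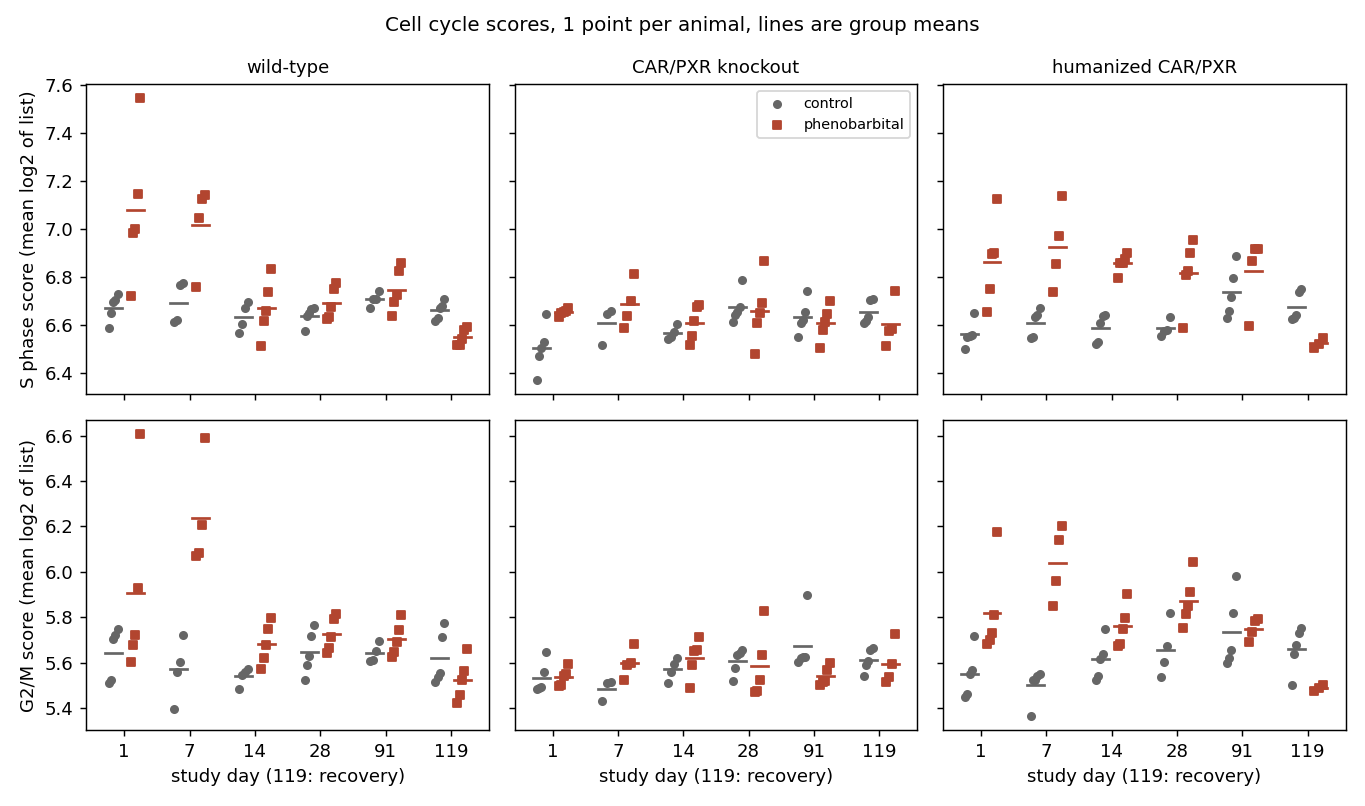
Mean log2 level of the S phase list (upper panels) and the G2/M list (lower panels) in each animal by study day, with 1 point per animal, horizontal lines at group means, circles for controls and squares for phenobarbital. The G2/M score with phenobarbital reached 6.24 in wild-type and 6.04 in humanized livers on day 7 against 5.60 in the knockout.

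Several wild-type responses changed between the start and the end of dosing. The phenobarbital effect on Sult3a1 was larger on day 91 than on day 1 by 4.84 ± 0.441, that on Cyp2b13 by 4.46 ± 0.295, that on Meg3 by 2.87 ± 0.228, that on Abcc4 by 2.64 ± 0.251 and that on Nebl by 2.54 ± 0.304. Meg3 was at −0.17 on day 1, rose by 1.59 on day 14, 2.77 on day 28 and 2.70 on day 91. The effect on cyclin Ccnd1 was smaller on day 91 by −1.23 ± 0.262 and that on the sulfate donor enzyme Papss2 by −0.69 ± 0.125. The smaller effects on Mcm5 (−1.20) and Fignl1 (−0.91) were lost without animal 2004 (adjusted p = 0.202 and 0.0711), and that on Cyp2c55 (−0.87) without animal 1003 (adjusted p = 0.174). With only the arrays of the compared groups, the calls for Papss2, Fignl1, Mcm5 and Cyp2c55 were also lost. The effect on the Dlk1-Dio3 list was larger on day 91 (2 of 3 genes, adjusted p = 2.11e-15), as was that on the female-biased list (4 of 9, and 5 larger and 1 smaller adjusted over the list alone; adjusted p = 1.96e-14). The effect on the S phase list was smaller (2 of 25, and 12 adjusted over the list alone; adjusted p = 1.1e-09), with 0 genes without 1001, 1003, 1023, 1025, 2004, 2021, 2023 or 2024, 1 without 1005, 1021, 1022, 2002 or 2022 and 5 without 2005, and so was that on cholesterol synthesis genes (0 of 20, and 15 adjusted over the list alone; adjusted p = 1.95e-17, and adjusted p = 0.0903 with an estimated correlation). The 8 pancreas acinar markers moved in the same contrast by a median of 2.12, with none passing. In all 55 genes passed (29 larger, 26 smaller), 36 without animal 2024, 36 without 1022, 35 without 1023, 101 without 2005 and 24 with only the arrays of the compared groups.

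By day, 1514 wild-type genes passed on day 1 (634 higher, 880 lower), 343 on day 7 (266 and 77), 1109 on day 14 (392 and 717), 700 on day 28 (456 and 244) and 269 on day 91 (183 and 86). Quantile normalization turned the split of day 14 to 486 higher and 389 lower. Without animal 2004 the count of day 1 was 889. The count of day 14 was 669 without 1013 and 565 without 1014, and that of day 91 was 162 without 1022. With only the arrays of the compared groups the counts of days 1, 14 and 28 were 755, 388 and 391.

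**Figure D2:**
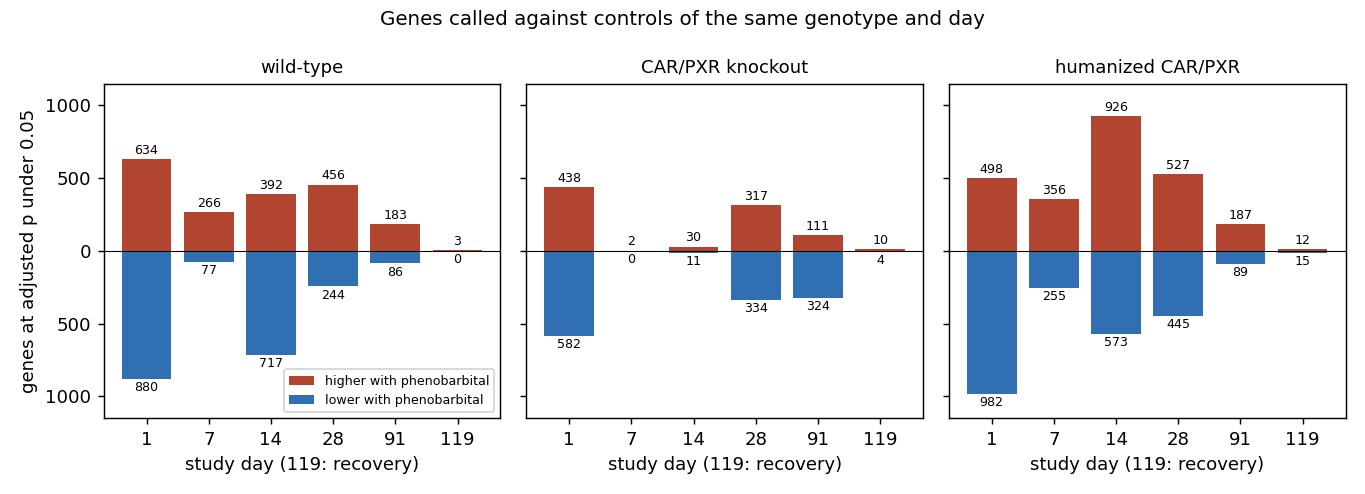
Number of genes with an adjusted p under 0.05 for phenobarbital against controls of the same day, by study day, in wild-type, knockout and humanized livers, with bars upward for genes higher with phenobarbital and downward for genes lower. Day 119, after recovery, had 3 genes in wild-type, 14 in knockout and 27 in humanized livers, against 1514, 1020 and 1480 on day 1.

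In the CAR/PXR knockout, the large inductions of drug metabolism genes were not seen (24 treated and 22 control animals). Cyp2b10 (0.17 ± 0.09), Cyp2c55 (0.15), Cyp2c29 (−0.04), Gadd45b (0.07), Meg3 (0.14), Rian (0.01), Mki67 (0.07), Cdk1 (0.03) and Top2a (0.07) did not pass as means of the dosing days. The knockout effect was below the wild-type effect by −6.33 ± 0.126 for Cyp2b10, −5.71 ± 0.106 for Cyp2c65, −4.24 ± 0.104 for Cyp2c55, −2.90 ± 0.201 for Sult3a1 and −2.59 ± 0.247 for Cyp2b9. It was also below it for Gadd45b (−1.14), Meg3 (−1.35) and Rian (−1.12), and above it for Cyp4a14 (2.01 ± 0.418), Hectd2os (1.07 ± 0.166), Rdh16f2 (1.06 ± 0.108) and Pde5a (1.00 ± 0.114). The higher effect on the retinoic acid hydroxylase Cyp26b1 (0.95) was lost without animal 3009 (adjusted p = 0.0948) and the lower effect on Mcm5 (−0.41) without animal 2004 (adjusted p = 0.0611). The differences for Mki67 (−0.33, adjusted p = 0.0957), Top2a (−0.27, adjusted p = 0.124) and Cdk1 (−0.19, adjusted p = 0.207) did not pass. The effects differed for 1696 genes (968 larger in the knockout, 728 smaller).

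Phenobarbital still changed other genes in the knockout. The fatty acid synthase Fasn rose by 0.66 ± 0.162, the transporter Slc16a5 by 0.62 ± 0.133, the phosphodiesterase Pde4b by 0.62 ± 0.11 and Gstm3 by 0.62 ± 0.083. The growth hormone signalling inhibitor Socs2 (−1.91 ± 0.314), Serpina4-ps1 (−1.47 ± 0.34), Slc25a30 (−1.06 ± 0.247) and Angptl4 (−0.90 ± 0.149) fell. In all 2473 genes passed (1090 higher, 1383 lower), of which 7 were at least 1.5-fold higher and 22 lower. With quantile normalization the split was 1371 higher and 1126 lower. Phase II genes rose in 14 and fell in 1 of 23 cases (adjusted p = 4.53e-06, and adjusted p = 0.158 with an estimated correlation), phase I genes rose in 6 of 22 (7 adjusted over the list alone; adjusted p = 0.00299, and adjusted p = 0.432 with an estimated correlation). Cholesterol synthesis genes rose in 6 of 20 (9 adjusted over the list alone; adjusted p = 0.000609, and adjusted p = 0.969 with an estimated correlation), and in 10 without animal 4013. Male-biased genes fell in 7 of 12 cases (8 adjusted over the list alone; adjusted p = 5.68e-05, and adjusted p = 0.306 with an estimated correlation).

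In the knockout neither cell cycle list passed as a mean of the dosing days. The S phase list had 4 of 25 genes higher and 2 lower (6 and 2 adjusted over the list alone; adjusted p = 0.314) and the G2/M list 2 of 19 higher and 1 lower (adjusted p = 0.924). Against the wild-type effect, that on S phase genes was lower for 8 genes, or 5 without animal 1022, 2004 or 2014 (adjusted p = 0.00153, and adjusted p = 0.317 with an estimated correlation) and that on G2/M genes for 7 (10 adjusted over the list alone; adjusted p = 2.54e-06, and adjusted p = 0.0893 with an estimated correlation), with Ect2 at −1.14. On day 1 the S phase list passed in the knockout with 1 gene higher (none adjusted over the list alone; adjusted p = 0.0191, and adjusted p = 0.929 with an estimated correlation), and was lost without animal 3001 (adjusted p = 0.0568). The count was 0 without 3001, 3002, 3003, 3004, 4001, 4002, 4003 or 4005. The S phase score on that day was 6.65 ± 0.01 (SD, n = 5) with phenobarbital and 6.51 ± 0.1 (SD, n = 5) without, a difference of 0.15. In it 4 treated animals lay above every control (exact permutation p = 0.0159, adjusted 0.0716). The G2/M list passed on none of the dosing days (adjusted p = 0.838, 0.156, 0.739, 0.96 and 0.285). The G2/M score on day 91 was 5.54 ± 0.04 (SD, n = 5) with phenobarbital and 5.67 ± 0.13 (SD, n = 5) without, every treated animal below every control (exact permutation p = 0.00794, adjusted 0.0476). The effects on phase I (18 of 22 genes lower, and 18 lower and 1 higher adjusted over the list alone; adjusted p = 2.26e-75), phase II (18 of 23, and 19 adjusted over the list alone; adjusted p = 2.65e-42), Dlk1-Dio3 (2 of 3, and 3 adjusted over the list alone; adjusted p = 1.15e-08) and female-biased genes (7 of 9, and 7 lower and 1 higher adjusted over the list alone; adjusted p = 1.99e-13) were also lower than in wild type, and passed with an estimated correlation. On periportal genes the effect was higher than in wild type for 8 of 11 (adjusted p = 1.21e-05).

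The knockout counts by day were unstable. On day 1, 1020 genes passed (438 higher, 582 lower), 390 without animal 3001, 602 without 4001, 509 without 4002, 653 without 4003 and 167 with only the arrays of the compared groups. Quantile normalization turned the split to 581 higher and 478 lower. The clock gene Dbp rose by 2.25 on that day, a call lost without animal 4003 (adjusted p = 0.108) and with the clock index as a covariate, which left 0.24. Of 17 lipogenesis genes 10 rose on that day (14 adjusted over the list alone; adjusted p = 7.24e-10, and adjusted p = 0.271 with an estimated correlation), and 5 without animal 3001. On day 7, 2 genes passed, both higher, none without 3009 or 4007, 1 without 3010 or 4009, 4 without 4010 and 0 with only the arrays of the compared groups, while 737 had an unadjusted p under 0.05 by limma. On day 14, 41 passed (30 higher, 11 lower), 2 without 3011, 4 without 3012, 73 without 3014, 21 without 4011, 8 without 4012, 64 without 4015 and 1 with only the arrays of the compared groups. The split under quantile normalization was 36 and 23. On day 28, 651 passed (317 higher, 334 lower), 354 without 3020, 309 without 4018, 315 without 4020, 414 with the clock index as a covariate and 8 with only the arrays of the compared groups. On day 91, 435 passed (111 higher, 324 lower), 258 without 3021, 230 without 3023, 275 without 3025, 206 without 4021, 154 without 4023 and 4 with only the arrays of the compared groups. Quantile normalization gave 109 higher and 138 lower.

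In humanized liver, phenobarbital again raised drug metabolism genes most (23 treated and 24 control animals over the dosing days). Cyp2b10 rose by 4.71 ± 0.088, from 7.75 ± 0.36 (SD, n = 5) in controls to 12.13 ± 0.39 (SD, n = 5) on day 1, Cyp2c65 by 4.39 ± 0.074 and Cyp2c55 by 2.84 ± 0.072. The membrane glycoprotein gene Prom1 rose by 3.44 ± 0.157, Abcc4 by 2.95 ± 0.08, Gstm3 by 2.64 ± 0.081, Sult3a1 by 2.05 ± 0.14 and the bile acid sulfotransferase Sult2a2 by 2.01 ± 0.097. Serpina4-ps1 (−1.47 ± 0.334), the taurine synthesis enzyme Csad (−1.42 ± 0.146), the iron hormone gene Hamp (−1.15 ± 0.149), and the lysosomal nuclease Dnase2a (−1.04 ± 0.118) fell most. Gadd45b rose by 1.21 ± 0.07, Meg3 by 1.38 ± 0.073, Rian by 1.08 ± 0.103, Mcm5 by 0.75 ± 0.097, Cdk1 by 0.33 ± 0.069, Mki67 by 0.30 ± 0.094 and Afp by 0.56 ± 0.09. Cyp3a11 rose by 0.14 and Cyp2c29 by 0.24, Glul fell by 0.12, and Top2a (0.18, adjusted p = 0.08), Axin2 (0.07), Cyp7a1 (0.14), Nr1i3 (−0.04) and Nr1i2 (−0.08) did not pass. Alb passed at −0.02, but not without animal 5004 (adjusted p = 0.0561) or with quantile normalization. In all 4084 genes passed (1880 higher, 2204 lower), and 83 were at least 1.5-fold higher and 32 lower. With quantile normalization the split was 2189 higher and 1962 lower.

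The humanized response of the lists covered phase I (19 of 22 genes higher, 1 lower, adjusted p = 5.5e-44), phase II (21 of 23 higher, 1 lower, the latter call lost without single animals such as 5001, adjusted p = 5.91e-39), Dlk1-Dio3 (3 of 3, adjusted p = 1.21e-06), NRF2 (6 of 10, adjusted p = 2.06e-10) and female-biased genes (7 of 9, adjusted p = 2.89e-09). Among the NRF2 genes the carbonyl reductase Cbr3 rose by 1.96, Nqo1 by 0.76 and Srxn1 by 0.71. Of 25 S phase genes 17 rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 4.51e-08, and adjusted p = 0.0308 with an estimated correlation), with Mcm6 up by 1.13. Of 19 G2/M genes 14 rose (16 adjusted over the list alone; adjusted p = 5.21e-06, and adjusted p = 0.089 with an estimated correlation), with Ect2 up by 0.84. Male-biased genes fell in 6 and rose in 1 of 12 cases (7 and 1 adjusted over the list alone; adjusted p = 0.00244, and adjusted p = 0.221 with an estimated correlation). Periportal genes fell in 6 and rose in 1 of 11 cases (adjusted p = 0.00335, and adjusted p = 0.172 with an estimated correlation), with Pck1 at −0.87, and hepatocyte markers fell in 5 of 8 (adjusted p = 0.00138). Of 12 hepatic transporters 5 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.00184). Cholesterol synthesis genes rose in 12 and fell in 1 of 20 cases, the latter lost without 6006 (adjusted p = 0.00413, and adjusted p = 0.621 with an estimated correlation), and 2 of 5 cholangiocyte markers rose (adjusted p = 0.00851, and adjusted p = 0.127 with an estimated correlation).

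By day, humanized S phase genes rose on day 1 in 9 of 25 cases (12 adjusted over the list alone; adjusted p = 3.32e-07, and adjusted p = 0.0729 with an estimated correlation), on day 7 in 7 (12 higher and 1 lower adjusted over the list alone; adjusted p = 2.12e-09), on day 14 in 7 (11 adjusted over the list alone; adjusted p = 8.69e-05, and adjusted p = 0.189 with an estimated correlation) and on day 28 in 5 with 1 lower (7 and 1 adjusted over the list alone; adjusted p = 5.95e-05, and adjusted p = 0.147 with an estimated correlation). On day 91 the list did not pass (adjusted p = 0.0813). The count of day 1 was 4 without animal 6003 and that of day 7 was 3 without 6008. G2/M genes rose on day 7 in 11 of 19 cases (13 adjusted over the list alone; adjusted p = 9.94e-17), with Ccnb2 up by 1.32 (adjusted p = 3.6e-06), Ect2 by 1.32 and Birc5 by 0.85. They rose in 4 cases on day 1 (6 adjusted over the list alone; adjusted p = 3.18e-05, and adjusted p = 0.154 with an estimated correlation) and in 2 on day 28 (4 adjusted over the list alone; adjusted p = 0.00287, and adjusted p = 0.315 with an estimated correlation), and did not pass on days 14 and 91 (adjusted p = 0.125 and 0.96). The G2/M count of day 1 was 2 without animal 5001, 5003, 6002 or 6003 and 1 without 5002, and that of day 28 was 1 without 6016 or 6017. Without treated animal 6003 the day 1 list passed (adjusted p = 0.00473). The day 1 calls for Mki67 (0.62), Ccna2 (0.44), Mad2l1 (0.31), Rrm2 (1.00) and Cdt1 (0.61) were lost without it (adjusted p = 0.203, 0.185, 0.151, 0.0795 and 0.0523). Its mean over the pancreas acinar markers was 12.28, against 4.98 to 6.66 in the other treated animals. The humanized S phase score differed by 0.30 on day 1, 0.32 on day 7 and 0.27 on day 14, with all 5, 4 and 5 treated animals above every control (exact permutation p = 0.00794 for each, adjusted 0.0476). The G2/M score on day 7 differed by 0.54 with all 4 treated animals above every control (exact permutation p = 0.00794, adjusted 0.0476).

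The humanized counts were 1480 on day 1 (498 higher, 982 lower), 611 on day 7 (356 and 255), 1499 on day 14 (926 and 573), 972 on day 28 (527 and 445) and 276 on day 91 (187 and 89). Quantile normalization gave 690 higher and 740 lower on day 1. The count of day 7 was 301 without animal 6006 and 403 without 6010, that of day 28 was 605 without 5017, and that of day 91 was 158 without 6021 and 167 without 6025. With only the arrays of the compared groups, the counts were 398, 341, 705, 422 and 89. The humanized effect was larger on day 91 than on day 1 for Sult2a2 (4.48 ± 0.305), Cyp2b9 (2.86 ± 0.541), Meg3 (2.75 ± 0.228), Sult3a1 (2.74 ± 0.441) and Prom1 (2.70 ± 0.494). It was smaller for Dbp (−4.46 ± 0.942), the lipogenic enzyme Me1 (−1.50 ± 0.318) and Tlcd2 (−0.91 ± 0.168). The smaller effects on Cidea (−2.38) and Per3 (−1.02) were lost without animals 6021 and 6023 (adjusted p = 0.143 and 0.0613), and those on Dbp, Per3 and Cidea with the clock index as a covariate or only the arrays of the compared groups. In all 220 genes passed (176 larger, 44 smaller), 126 without 6003, 90 without 6022, 119 without 5022, 135 without 5024, 336 with the clock index as a covariate and 29 with only the arrays of the compared groups. With quantile normalization the split was 119 larger and 63 smaller.

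**Figure D3:**
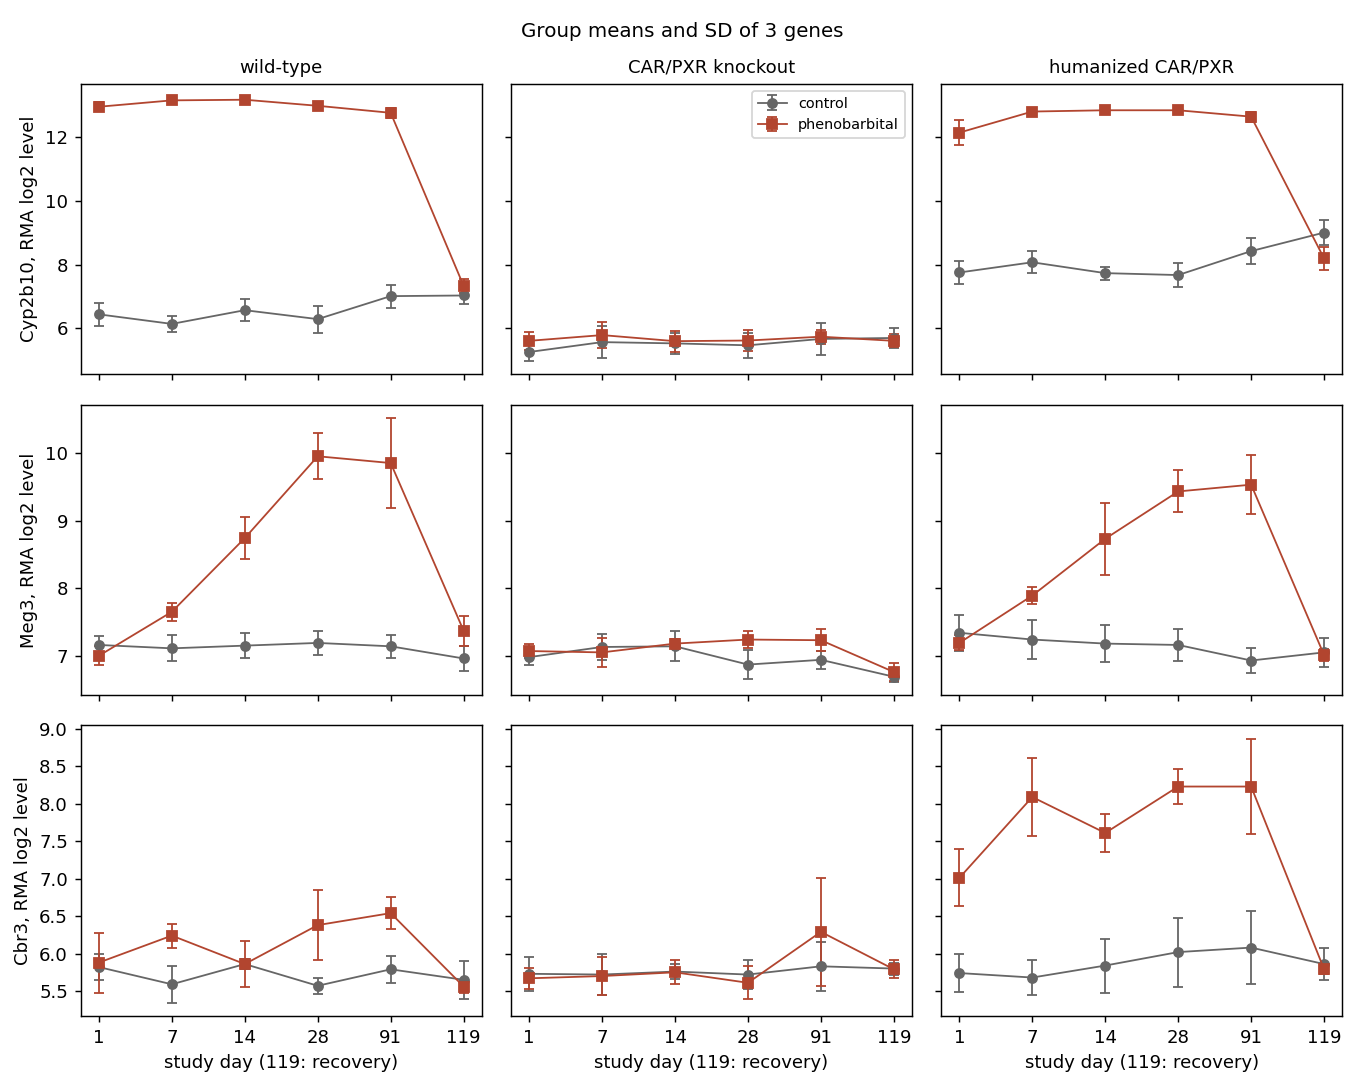
Group mean RMA log2 level of Cyp2b10, Meg3 and Cbr3 by study day in wild-type, knockout and humanized livers, with bars of 1 SD over the 3 to 5 animals of a group, circles for controls and squares for phenobarbital. Meg3 with phenobarbital reached 9.95 in wild-type and 9.43 in humanized livers on day 28 and lay at 7.37 and 7.01 on day 119.

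Wild-type and humanized responses, which share no control arrays, overlapped widely. Of the 3971 genes called in wild type, 92.9% had the same sign in humanized mice, and of the 4084 humanized genes 93.3% had the same sign in wild type. In both, 2469 genes passed, 2454 of them with the same sign, where 994 were higher and 1460 lower against 221.3 and 433.9 if the lists were independent. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.805, against 0.342 for wild type with the knockout and 0.469 for humanized with the knockout.

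The humanized effect nevertheless differed from the wild-type effect for 237 genes (139 larger, 98 smaller). It was larger for Prom1 by 2.63 ± 0.224 (3.44 against 0.81), for Sult2a2 by 1.94 ± 0.138 (2.01 against 0.07), for Cbr3 by 1.51 ± 0.127 (1.96 against 0.45), for Abcc4 by 1.14 ± 0.114 (2.95 against 1.81) and for the acyl-CoA thioesterase Acot1 by 0.86 ± 0.137 (−0.06 against −0.93). It was smaller for Cyp2b10 by −1.79 ± 0.125, Cyp2c55 by −1.55 ± 0.103, Cyp2b13 by −1.33 ± 0.133, Cyp2c65 by −1.29 ± 0.105 and Cyp2b9 by −1.21 ± 0.245. Humanized controls had higher Cyp2b10 (1.53) and Cyp2c55 (1.30) than wild-type controls over the 6 days. Treated Cyp2b10 levels on day 28 were 12.83 ± 0.11 (SD, n = 5) in humanized and 12.97 ± 0.12 (SD, n = 5) in wild-type livers, where the highest value of any probe set on any array was 15.07. The larger effect on Afp (0.44) was lost without animal 1022 (adjusted p = 0.0848). Effects on Gadd45b (−0.01), Meg3 (−0.10), Rian (−0.06), Mki67 (−0.10), Cdk1 (0.10), Top2a (−0.16) and Mcm5 (0.08) were not shown to differ. Phase I effects were lower in 8 of 22 genes (10 adjusted over the list alone; adjusted p = 1.52e-27) and NRF2 effects higher in 4 of 10 (6 adjusted over the list alone; adjusted p = 1.04e-07). Phase II effects were lower in 6 of 23 (3 higher and 9 lower adjusted over the list alone; adjusted p = 0.000349, and adjusted p = 0.199 with an estimated correlation), with Sult1e1 at −1.11. The S phase list (1 of 25 higher, adjusted p = 0.161) and the G2/M list (0 of 19 by limma, and 1 higher adjusted over the list alone; adjusted p = 0.696) did not pass.

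Against the knockout effect, the humanized effect was larger for Cyp2b10 (4.54 ± 0.126), Cyp2c65 (4.42 ± 0.106), Prom1 (3.46 ± 0.224), Abcc4 (2.71 ± 0.114) and Cyp2c55 (2.69 ± 0.103). It was smaller for Cyp26b1 (−1.22 ± 0.332), Hectd2os (−1.02 ± 0.165), Hamp (−0.99 ± 0.213), Olig1 (−0.98 ± 0.158) and the retinol esterifying enzyme Lrat (−0.95 ± 0.173). Gadd45b (1.14), Meg3 (1.24), Rian (1.07), Mcm5 (0.49) and Afp (0.49) also had larger effects, while those for Cdk1 (0.30) and Glul (−0.13) were lost without animals 6008 and 3025 (adjusted p = 0.0589 and 0.0677). S phase effects were higher in 9 of 25 genes (12 adjusted over the list alone; adjusted p = 2.05e-06) and G2/M effects in 6 of 19 (8 adjusted over the list alone; adjusted p = 2.13e-06), both with adjusted p = 0.067 with an estimated correlation. G1 and growth control effects were higher in 4 and lower in 1 of 18 genes (adjusted p = 0.0269, and adjusted p = 0.0985 with an estimated correlation). The lower 1 was lost without animal 3010, 3013, 4015, 4025, 5017 or 6025. In all 1281 genes passed (714 larger, 567 smaller).

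After 4 weeks without phenobarbital few genes still differed from controls. In wild-type livers 3 genes passed, all higher, and 574 had an unadjusted p under 0.05 by limma. Nebl was higher by 1.19 ± 0.209, Serpinb1a by 1.37 ± 0.291 and Cyp2b13 by 1.13 ± 0.202, the calls for the latter pair lost without animals 1029 and 2029 (adjusted p = 0.366 and 0.166). Without animal 2029 only 1 gene passed. Cyp2b10 was at 7.33 ± 0.23 (SD, n = 5) after phenobarbital and 7.03 ± 0.28 (SD, n = 5) in controls. The S phase list was lower with no gene passing (1 lower adjusted over the list alone; adjusted p = 0.000262, and adjusted p = 0.505 with an estimated correlation), and its score differed by −0.11 with every treated animal below every control (exact permutation p = 0.00794, adjusted 0.0476). The G2/M list was called lower with none passing (adjusted p = 0.0229, and adjusted p = 0.73 with an estimated correlation), a call lost without animal 1027, 1029, 2026 or 2029 (adjusted p = 0.208 at most). The pancreas acinar markers moved by a median of −1.36 in the same contrast with none passing (adjusted p = 0.000262, and adjusted p = 0.717 with an estimated correlation), a call lost without animal 1026 or 1028 (adjusted p = 0.318 and 0.107). Also with none passing, interferon response genes were lower (median −0.17), as were periportal genes (median −0.07; adjusted p = 0.000814 and 0.014, and adjusted p = 0.505 and 0.601 with an estimated correlation), the latter lost without 1028, 2028 or 2030 (adjusted p = 0.147 at most). Endothelial markers were higher (median 0.10, adjusted p = 0.0229, and adjusted p = 0.73 with an estimated correlation), lost without 1026, 1027, 1030, 2027 or 2028 (adjusted p = 0.615 at most).

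In knockout livers 14 genes passed on day 119 (10 higher, 4 lower), with 894 at an unadjusted p under 0.05. The chemokine gene Cxcl1 was higher by 2.98 ± 0.361, Socs3 by 2.27, Saa1 by 2.07, Fos by 1.12 and Junb by 0.97, and Zfp979 (−1.37), Gpx6 (−0.80), Pdilt (−0.68) and Mycbp (−0.24) were lower. All of these but Cxcl1 were lost when 1 animal was left out, Fos without 4027 (adjusted p = 0.42), Pdilt without 4026 (adjusted p = 0.199) and the others without 4028 (adjusted p = 0.21 to 0.491). The count was 1 without animal 4028, 4 without 3026, 7 without 3027, 8 without 3028, 9 without 3030, 9 without 4026 and 57 without 4030, and it was 0 with only the arrays of the compared groups, so that Cxcl1 was lost there too. The acute phase list rose with 2 of 19 genes higher (15 adjusted over the list alone; adjusted p = 8.73e-25). That count was 0 without animal 3026, 3027, 3028 or 4028, 1 without 3030 or 4026, 8 without 4027 and 7 without 4030, and the list passed each time. In humanized livers 27 passed (12 higher, 15 lower), with 1281 at an unadjusted p under 0.05, including Peg3 (0.72), Cdkn2c (0.49), Ccdc84 (0.43), Gstm2 (−0.97), Gstm3 (−0.92) and Cyp2c54 (−0.62). Each of these was lost when 1 animal was left out, Peg3 without 6026 and 6030 (adjusted p = 0.171) and the others without 6027 (adjusted p = 0.151 to 0.568). The count was 1 without animal 6027, 8 without 5026, 0 without 5029, 14 without 5030, 47 with the clock index as a covariate, 117 with arrays 6026 and 6030 as 2 samples and 0 with only the arrays of the compared groups. Humanized phase I (2 of 22 lower, and 4 adjusted over the list alone; adjusted p = 1.59e-06, and adjusted p = 0.0638 with an estimated correlation) and phase II genes (2 of 23 lower, and 6 adjusted over the list alone; adjusted p = 1.91e-07, and adjusted p = 0.062 with an estimated correlation) lay below controls. The phase I count was 0 without animal 5026, 5029, 5030, 6027 or 6029 and 1 without 6026 and 6030. The phase II count was 0 without 5029 or 6027 and 1 without 5027 or 6029, and both lists passed each time. The humanized S phase and G2/M lists were called lower as well, with no gene passing (1 S phase gene lower adjusted over the list alone; adjusted p = 0.000162 and 0.000687, and adjusted p = 0.338 and 0.373 with an estimated correlation). Their scores differed by −0.15 (exact permutation p = 0.0179, the smallest the design allows, adjusted 0.0716) and −0.17 (exact permutation p = 0.0536, adjusted 0.121). In the knockout these lists did not pass (adjusted p = 0.587 and 0.983). Beside them moved the humanized Wnt and perivenous list (3 of 16 lower, and 4 adjusted over the list alone; adjusted p = 7.86e-05, and adjusted p = 0.176 with an estimated correlation), with 0 lower without 5029 or 6027 and 1 without 5030 or without 6026 and 6030. With none passing, cholesterol synthesis (median −0.22) and ER stress genes (median −0.20) were lower (adjusted p = 6.95e-06 and 0.00945, and adjusted p = 0.379 with an estimated correlation for each), lost without 6027 (adjusted p = 0.0695 and 0.401), the latter also without 5028. Gluconeogenesis genes (median 0.14, adjusted p = 0.0498, and adjusted p = 0.379 with an estimated correlation) were higher, lost without 5026, 5029, 5030, 6027, or 6026 and 6030 (adjusted p = 0.448 at most). G1 and growth control genes rose in 1 of 18 cases (4 adjusted over the list alone; adjusted p = 0.0487, and adjusted p = 0.338 with an estimated correlation). That call was lost without 5026, 5027, 5029, 5030 or 6029 (adjusted p = 0.295 at most), and the count was 0 without 5026, 5029, 5030, 6027 or 6029 and 2 without 6026 and 6030. Kupffer markers (median −0.34, adjusted p = 7.86e-05, and adjusted p = 0.379 with an estimated correlation) were lost without 6027 (adjusted p = 0.0671). Pancreas acinar markers (median −0.97, adjusted p = 0.042, and adjusted p = 0.608 with an estimated correlation) were lost without 5028, 6029, or 6026 and 6030 (adjusted p = 0.757 at most). In the knockout the pancreas list was called too (median −1.01, adjusted p = 0.0497, and adjusted p = 0.801 with an estimated correlation) and lost without 3028, 4026, 4028 or 4030 (adjusted p = 0.897 at most). Knockout phase I, phase II, bile acid, PPARα, Wnt and perivenous and B and plasma cell lists were called lower with no gene passing, in none with an estimated correlation, and each was lost when 1 animal was left out, in most cases 4028.

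Untreated livers differed between genotypes as well, over all 6 days. Knockout controls had higher Cyp4a14 (1.96 ± 0.274), Cyp2c55 (1.92 ± 0.068), Socs2 (1.75 ± 0.289), the cholesterol synthesis enzyme Sqle (1.41 ± 0.14) and the phospholipase Pla2g12a (1.40 ± 0.06) than wild-type controls. Besides the targeted genes, Nr1i2 (−3.94 ± 0.052) and Nr1i3 (−3.48 ± 0.049), they had lower Slco1a4 (−2.78 ± 0.085), an organic anion transporter that PXR induces, lower Nnt (−1.35 ± 0.04), the mitochondrial nicotinamide nucleotide transhydrogenase, and lower Cyp2c54 (−1.17 ± 0.054). In all 2829 genes passed (1454 higher, 1375 lower), and quantile normalization gave 1252 higher and 1785 lower. Cholesterol synthesis genes were higher in 18 of 20 cases (adjusted p = 1.4e-20, and adjusted p = 0.0946 with an estimated correlation) and phase II genes higher in 16 and lower in 1 of 23 (17 and 1 adjusted over the list alone; adjusted p = 2.9e-16). Pancreas acinar markers were lower by a median of −0.90, with none of 8 passing (8 adjusted over the list alone; adjusted p = 0.0287, and adjusted p = 0.833 with an estimated correlation). This call was lost without animal 1002, 1011, 1012, 1021, 1026 or 1028 (adjusted p = 0.0754 at most). All 8 markers passed without 1004, 1013, 1014, 1030, 3019 or 3028, and 1 to 6 without 1005, 1023, 1025, 1027, 1029, 3021 or 3024.

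Humanized controls had higher Cyp4a14 (2.16 ± 0.267), Serpinb1a (1.58 ± 0.124), Cyp2b10 (1.53 ± 0.081) and Dct (1.34 ± 0.086) than wild-type controls, and besides Nr1i2 (−3.76 ± 0.05) and Nr1i3 (−3.33 ± 0.048) lower Tmem223 (−1.56 ± 0.039). The clock output gene Dbp was higher by 1.91 ± 0.274, and turned to −0.14 with the clock index as a covariate. The pancreatic enzyme genes Cpb1 (−1.91 ± 0.605) and Cpa1 (−1.49 ± 0.436) were lower, and the call for Cpb1 was lost with the pancreas acinar mean as a covariate, at −0.06. All 8 pancreas acinar markers were lower, by a median of −1.10 (adjusted p = 0.0117, and adjusted p = 0.581 with an estimated correlation). The clock index, the mean log2 level of Arntl, Npas2, Clock and Nfil3 minus that of Dbp, Per3, Nr1d1, Nr1d2, Ciart and Tef, averaged 0.64 in humanized, 1.38 in knockout and 1.95 in wild-type controls of the dosing days. In all 3541 genes passed (1459 higher, 2082 lower), with 1757 higher and 1763 lower under quantile normalization. Phase I genes were higher in 14 and lower in 2 of 22 cases (adjusted p = 3.06e-15) and phase II genes higher in 15 and lower in 1 of 23 (18 and 1 adjusted over the list alone; adjusted p = 8.02e-16). Cholesterol synthesis genes were higher in 14 of 20 (15 adjusted over the list alone; adjusted p = 3.11e-11, and adjusted p = 0.301 with an estimated correlation).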

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

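Calls lost when 1 animal was left out are named in the report. Of the tests in this part, only the splits with a shared day or genotype difference subtracted were chosen after the result was seen. In 8 of 136 groups, over the S phase score, the G2/M score, Cyp2b10 and Meg3, 1 animal stood far from the others of its group by Dixon's test, and chance alone gives about 1 in 20 groups, or 6.8 here. The S phase score stood apart in treated humanized animal 6022 of day 91 (6.60). The G2/M score did so in knockout control 3025 of day 91 (5.90), treated humanized animal 6003 of day 1 (6.17) and humanized control 5006 of day 7 (5.36). Cyp2b10 stood apart in wild-type control 1016 (5.55) and treated wild-type animal 2019 (13.18), both of day 28. Meg3 stood apart in treated wild-type animal 2030 of day 119 (7.75) and in knockout control 3018 of day 28 (7.24).

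The phenobarbital effects of the humanized and wild-type mice differed, by limma's test of the difference, for 237 genes. Prom1 (2.63), Sult2a2 (1.94), Cbr3 (1.51), Abcc4 (1.14) and Acot1 (0.86) had the larger humanized effects, and Cyp2b10 (−1.79), Cyp2c55 (−1.55), Cyp2b13 (−1.33), Cyp2c65 (−1.29) and Cyp2b9 (−1.21) the smaller. With genotype exchanged within treatment and day, only the real split of 100, or 1, called as many and the highest other called 56, but such splits hold the genotype differences that both arms share and so decide nothing about chance. With that difference subtracted for each gene and day, 2 of 100 splits, the real one included, called as many and the other of them called 298. That share lies under 0.05 but does not exclude chance.

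Knockout and wild-type effects differed for 1696 genes. Cyp4a14 (2.01), Hectd2os (1.07), Rdh16f2 (1.06), Pde5a (1.00) and Cyp26b1 (0.95) lay above the wild-type effect. Cyp2b10 (−6.33), Cyp2c65 (−5.71), Cyp2c55 (−4.24), Sult3a1 (−2.90) and Cyp2b9 (−2.59) lay below it. The real split was the 1 of 100 with as many genes and the highest other called 2, which again decides nothing. With the shared genotype difference subtracted it was also 1 of 100 and the highest other called 1, which argues against chance in that test. Humanized and knockout effects differed for 1281 genes, in 1 of 100 splits with 71 in the highest other, and with the shared difference subtracted in 1 of 100 with 27, of which the latter argues against chance. Cyp2b10 (4.54), Cyp2c65 (4.42), Prom1 (3.46), Abcc4 (2.71) and Cyp2c55 (2.69) had the larger humanized effects, and Cyp26b1 (−1.22), Hectd2os (−1.02), Hamp (−0.99), Olig1 (−0.98) and Lrat (−0.95) the smaller.

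Between day 91 and day 1 the wild-type effect differed for 55 genes. It was larger on day 91 for Sult3a1 (4.84), Cyp2b13 (4.46), Meg3 (2.87), Abcc4 (2.64) and Nebl (2.54). It was smaller for Ccnd1 (−1.23), Mcm5 (−1.20), Fignl1 (−0.91), Cyp2c55 (−0.87) and Papss2 (−0.69). In 9 of 100 splits of the days as many genes were called, and the highest other called 475, but these splits hold the day differences that both arms share and so decide nothing about chance. With that difference subtracted, only the real split, 1 of 100, called as many (highest other 15), which argues against chance in that later test.

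The humanized effect differed between day 91 and day 1 for 220 genes. Sult2a2 (4.48), Cyp2b9 (2.86), Meg3 (2.75), Sult3a1 (2.74) and Prom1 (2.70) had larger effects on day 91, and Dbp (−4.46), Cidea (−2.38), Me1 (−1.50), Per3 (−1.02) and Tlcd2 (−0.91) smaller ones. Here 5 of 100 splits of the days called as many genes (highest other 738), which again did not exclude chance. With the shared day difference subtracted, 1 of 100 called as many, the real one (highest other 36), which argues against chance in that test.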

How the results depend on the processing

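Of the results in this part, the fits with the clock index or the pancreas acinar mean as a covariate, with arrays 6026 and 6030 as 2 samples and without arrays 4019 and 4024, and the list tests with animals left out, were chosen only after the result was seen. Of 1355 called values of named genes, the call was kept for 1275 with no filter on dim genes, 1317 with quantile normalization, 1345 with trend and robust, 1307 with array weights, 1218 with the largest-variance probe set, 1048 with only the arrays of the compared groups, 1241 with the clock index, 1312 with the pancreas mean, 1333 without arrays 4019 and 4024, 1353 with arrays 6026 and 6030 apart, and 1001 whichever animal was left out. Of 263 list calls, 255 were kept with no filter, 245 with quantile normalization and 199 whichever animal was left out. The cause of the changes given here was not tested unless stated. Genes of low signal were not tested in the chosen fit, so that changes near background stay unseen. No paired analysis was possible because animal numbers are unique to 1 group.

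A minimum of 1.5-fold left 130 wild-type, 29 knockout and 115 humanized genes of the dosing-day means, fewer by its construction. By day from 1 to 91 it left 163, 124, 166, 143 and 82 in wild type, 86, 1, 14, 68 and 24 in the knockout, and 136, 137, 175, 184 and 85 in humanized mice, with 5 on humanized day 119. The humanized minus wild-type, knockout minus wild-type and humanized minus knockout differences held 26, 109 and 78 genes, the knockout and humanized controls 96 and 94, and the wild-type and humanized day 91 minus day 1 differences 30 and 74. The share of wild-type genes with the same sign in humanized mice, 92.9%, became 98.5% at 1.5-fold, 92.8% with no filter and 92.3% with quantile normalization.

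All kept probe sets are more features than genes, and gave 6959, 4638 and 7805 calls for the wild-type, knockout and humanized dosing-day means. They gave 2453 and 418 on wild-type days 1 and 91, 1703, 101 and 982 on knockout days 1, 14 and 28, 2576, 977, 2420 and 1547 on humanized days 1, 7, 14 and 28, and 5 and 30 on wild-type and knockout day 119. The 3 genotype differences, in the order above, had 512, 2750 and 1977 and the knockout and humanized controls 5285 and 7244.

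Only the arrays of the compared groups, which leave fewer samples to estimate the spread, gave 755, 388 and 391 genes on wild-type days 1, 14 and 28. They gave 167, 0, 1, 8 and 4 on knockout days 1 to 91 and 398, 341, 705, 422 and 89 on humanized days 1 to 91. On day 119 they gave 0 in the knockout and 0 in humanized mice by limma, and for the wild-type and humanized day 91 minus day 1 differences 24 and 29. Array weights gave 747 and 522 genes on wild-type days 7 and 91, 24 and 361 on knockout days 7 and 14, and 7, 49 and 311 on wild-type, knockout and humanized day 119. They gave 411 for the humanized minus wild-type difference and 109 for the wild-type day 91 minus day 1 difference. Quantile normalization gave 247 on knockout day 91 and trend with robust 22 on knockout day 119. The clock index as a covariate gave 414 on knockout day 28, 47 on humanized day 119 and 336 for the humanized day 91 minus day 1 difference. Arrays 6026 and 6030 as 2 samples gave 117 on humanized day 119. With an estimated correlation the dosing-day mean lost the wild-type S phase list (adjusted p = 0.0922), the wild-type G2/M list (adjusted p = 0.0581) and the humanized G2/M list (adjusted p = 0.089).

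Leaving out 1 animal at a time, the counts of the dosing-day means ranged from 3752 to 4082 in wild type, 2118 to 2649 in the knockout and 3798 to 4121 in humanized mice. In wild type they ranged from 889 to 1729 on day 1, 258 to 303 on day 7, 565 to 1176 on day 14, 501 to 649 on day 28, 162 to 294 on day 91 and 1 to 4 on day 119. In the knockout the ranges were 390 to 1372, 0 to 4, 2 to 73, 309 to 790, 154 to 607 and 1 to 57, and in humanized mice 994 to 1558, 301 to 595, 1096 to 1454, 605 to 1091, 158 to 300 and 0 to 35. The humanized minus wild-type difference ranged from 213 to 302, knockout minus wild-type from 1546 to 1779 and humanized minus knockout from 1204 to 1360. Knockout controls ranged from 2530 to 2925, humanized controls from 3331 to 3663, and the day 91 minus day 1 differences from 35 to 101 in wild type and 90 to 312 in humanized mice.

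Few named genes reversed. Alb in the humanized dosing-day mean came to 0.00 with quantile normalization. In humanized against wild-type controls, the clock index as a covariate turned Dbp to −0.14, Cdkn1a to 0.06 and Irs2 to 0.06, and the pancreas acinar mean as a covariate turned Cel to 0.04 and Prss2 to 0.05. The largest-variance probe set, which measures another part of the transcripts, reversed 20 values. In dosing-day means they were Ccn1 (0.00), Txnrd1 (−0.24), Clock (0.04) and Epcam (−0.04) in the knockout and Ccn1 (−0.08) and Epcam (−0.09) in humanized mice. On single days they were Egfr (0.20) and Met (0.03) on wild-type day 1, Fen1 (−0.19) on wild-type day 14, Alad on knockout day 1 (−0.33) and humanized days 1 (−0.17) and 14 (−0.02), Uros on knockout day 28 (−0.02), Etnppl on humanized day 28 (0.37) and Map3k4 on humanized day 119 (−0.13). In differences they were Gsr in humanized minus wild-type (−0.02), Elovl6 (−0.18), Uros (0.05) and Tspan8 (−0.10) in humanized controls, and Aen in wild-type day 91 minus day 1 (0.01). Other probe sets also gave the opposite sign past the threshold for Fgfr4 in the wild-type mean (0.11 against −0.25) and for Egfr in the knockout mean (0.11 against −0.65) and on knockout day 91 (0.34 against −1.41).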

Other observations

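Of the tests in this part, those of the near-identical arrays, of the genes beside the targeted loci and of Nnt, the fits with the clock index as a covariate and without arrays 4019 and 4024, and the list tests with animals left out, were chosen only after the result was seen. On day 1 the cholesterol synthesis list was called in each genotype at the preset correlation, and in none with an estimated one. Of 20 cholesterol synthesis genes 17 rose in wild-type liver (18 adjusted over the list alone; adjusted p = 1.32e-20, and adjusted p = 0.0519 with an estimated correlation), with the squalene epoxidase Sqle up by 2.11 ± 0.322 (SE, n = 5 and 5). In the knockout 6 rose (14 adjusted over the list alone; adjusted p = 9e-09, and adjusted p = 0.836 with an estimated correlation), as did 6 in humanized liver (16 adjusted over the list alone; adjusted p = 3.32e-07, and adjusted p = 0.352 with an estimated correlation). The knockout count was 2 without animal 3001, and the humanized count 3 without 5004 and 2 without 5005, 6001, 6003 or 6005, while the lists passed. Lipogenesis genes rose in 7 of 17 cases in humanized liver on that day (9 adjusted over the list alone; adjusted p = 5.26e-06, and adjusted p = 0.29 with an estimated correlation). The count was 4 without 5004 or 6001 and 3 without 6002 or 6003. In wild-type liver 3 of these genes rose (6 adjusted over the list alone; adjusted p = 0.00153, and adjusted p = 0.507 with an estimated correlation), 1 without animal 2003 or 2004 and 6 without 2005. The clock index on day 1 lay between −0.74 and 1.58 in treated and 1.22 and 1.79 in control knockout livers, and between −2.23 and 1.55 in treated and 0.93 and 1.47 in control humanized livers. In wild-type livers it was 1.54 ± 0.26 (SD, n = 5) with phenobarbital and 2.06 ± 0.22 (SD, n = 5) without. Differences between genotypes on single days were not tested.

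Female-biased liver genes rose in wild type on days 7, 14, 28 and 91 in 5, 4, 6 and 4 of 9 cases (5, 5, 7 and 5, with 1 lower on day 28, adjusted over the list alone; adjusted p = 1.68e-09, 5.25e-06, 1.64e-19 and 1.05e-25) and in humanized liver in 4, 4, 5 and 6 (adjusted p = 7.41e-05, 1.8e-05, 7.03e-13 and 5.8e-21), all also called with an estimated correlation. On day 1 the list did not pass (adjusted p = 0.0698 and 0.269). The wild-type count of day 7 was 3 without 1007, 2006 or 2007 and 2 without 1006, 1008, 1010 or 2008, and the humanized one 1 without 6007. Sult3a1 was up on day 91 by 5.13 and 2.99. In the knockout the list passed on none of the dosing days (adjusted p = 0.224 at least). The knockout showed 5 of 22 phase I genes higher on day 91 (8 adjusted over the list alone; adjusted p = 2.85e-08). The phase I count was 2 without animal 3025 and 3 without 4023, and the list passed each time. Cyp1a2 (0.70) passed whichever animal was left out. The Dlk1-Dio3 list rose in wild-type liver on day 14 in 3 of 3 genes (adjusted p = 1.14e-06), or 1 without animal 1011 or 1013, and on days 28 and 91 (adjusted p = 1.52e-17 and 2.5e-18). In humanized liver it rose on days 7, 14, 28 and 91 (adjusted p = 0.0111, 8.36e-05, 8.03e-10 and 1.21e-18).

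A pair of arrays from 1 group and a pair from different days were nearly identical. Over bright genes the larger of both SDs of the log2 difference was 0.0613, below 0.1221, the lowest of all other pairs. Over all tested genes none differed by over 2-fold, where 10 or more did in every other pair. These values are consistent with the same RNA hybridised on both arrays, and for animals 4019 and 4024 that would put 1 label in doubt.

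Phenobarbital changed 2473 genes in livers without CAR and PXR. Sampling at another clock phase was hardly tested, as the clock index averaged 1.49 in treated and 1.38 in control knockouts of the dosing days. As a covariate it gave 1.001 times the count, with 2442 shared genes of the same sign, which cannot decide. Arrays 4019 and 4024 are argued against, since without them the count was 0.954 times as large, with 2222 shared genes of the same sign. A response through other receptors is an untested hypothesis.

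Knockout controls differed from wild-type controls in genes beside the targeted ones and in Nnt. A local effect or carried-over DNA at the Nr1i3 and Nr1i2 loci cannot be told apart from other causes by counts, which ignore effect size. Of the 40 nearest tested genes 12 were called, 9 of them at Nr1i3. A share of 0.1861 of 10000 random pairs of windows held as many. Tomm40l, a neighbour of Nr1i3, was at −1.10 in knockout and 0.79 in humanized controls, and Pcp4l1 on its other side at −0.41 (limma adjusted p = 2.48e-05) and 0.96 (limma adjusted p = 2.19e-21). For Nnt a local effect at either locus is excluded, since 0 of the 2 loci lie on its chromosome. A substrain variant in Nnt, such as the deletion known in C57BL/6J mice, is a candidate explanation that cannot be told apart from genotype, as all 55 knockout animals lay below all 111 others with a gap of 0.54, whatever the treatment and day.

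Splits with treatment exchanged within days were counted for each phenobarbital comparison. Chance is excluded for the dosing-day means, with only the real split of 100 as large. The real counts and the highest of the other splits were 3971 and 575 in wild type, 2473 and 270 in the knockout and 4084 and 672 in humanized mice. In wild type 1 split of 100 was as large on days 1 (1514, highest other 812), 14 (1109 and 841), 28 (700 and 224) and 91 (269 and 164). On day 7 it was 1 of 35 (343 and 42). On day 119 it was 1 of 100, but the counts of 3 and 2 are too close to decide. In the knockout 1 of 100 was as large on days 1 (1020 and 576), 14 (41 and 21), 28 (651 and 238) and 91 (435 and 371). With only the compared groups these were 167, 1, 8 and 4. Chance is open on days 7 (2 of 35, 2 and 3) and 119 (3 of 100, 14 and 29). In humanized mice it is excluded with 1 of 100 on days 1 (1480 and 598), 7 (611 and 244), 14 (1499 and 628), 28 (972 and 953) and 91 (276 and 178), but not on day 119, where 3 of 56 called as many (27 and 56). For the controls, with genotype exchanged within days, 1 of 100 splits was as large for the knockout (2829, highest other 16) and for humanized mice (3541 and 27), which argues against chance.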
